A study of Homo sapiens with 6 samples.

How the data were processed

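RNA was measured on 6 whole-transcript Affymetrix arrays, 1 per culture of TC71 cells, with 3 cultures treated with the vehicle DMSO and 3 with BEZ235 for 16 h. Per the labels' protocols, RNA was column-purified with a DNase step, fragmented and biotinylated with a whole-transcript terminal labeling kit. The labels call the 3 samples of each group biological replicates. They give no concentration of BEZ235, no culture day and no hybridisation batch, so neither dose nor batch was analysed here.

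The deposited values are log2 signals, 1 column per array, and the authors made them with RMA, per the submitters' processing notes. RMA corrects background, equalises the distributions of the arrays and summarises the probes of a feature on the log2 scale; its version, software and parameters were not given in the sources used here. Because the distributions are equalised, a change in the total amount of RNA per cell is not visible in these values, and every change is relative to the rest of the array. The median log2 value of an array ran from 5.63 to 5.74. The table carries no detection call and no measure of background for each feature, so no dim feature was left out of the main test, and a fold change of a dim feature understates the change. The number of arrays limits the precision; 3 arrays against 3 left 4 residual degrees of freedom for each feature before the spread was shared across features.

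The table had 70523 entries, of which 67528 carried an identifier of a transcript cluster and were tested; the 2995 others (control probes and single probe selection regions or junctions) were left out. Each transcript cluster has 1 value over its exons, and the single probe selection regions and junctions carry no gene in the annotation used here, so exon usage and splicing were not tested, although the series title names splicing. Gene names came from the platform annotation: 23781 features had 1 gene symbol, 1543 had several and 42204 had none. Features with several symbols or none were tested and counted but not named. For each of the 22465 symbols, the feature with the highest mean over all 6 arrays stood for the gene; 479 symbols had more than 1 feature, and in 0 of them were features called in both directions. Symbols were updated through a RefSeq gene table of the GRCh38 assembly, used for names only; no genome build is stated for the values and no coordinates are given. Of 1011 different genes in the lists, 857 were measured, 34 of them through a synonym. Features with the same value on all 6 arrays as an earlier feature numbered 1675, many of them copies on alternate haplotypes.

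The comparison was BEZ235 minus DMSO, fitted with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over all 67528 features and a threshold of adjusted p under 0.05. Fold changes are on the log2 scale, with the moderated standard error (SE); levels are means ± SD over 3 arrays. Gene lists were tested with limma's camera on 1 feature per gene, with the inter-gene correlation preset at 0.01 and adjustment over the 35 lists with at least 5 measured members. For each list, camera with a correlation estimated from the data and fry were run as well, and its median was placed among 10000 random lists of the same size matched on mean level in 20 bins. The number of members past the threshold is given over all features and also adjusted over the list alone. The list of mitochondrially encoded transcripts had 0 members matched by symbol and was not tested. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

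The design, the 36 lists, the alternatives and the rule for named genes were written before the data were examined. The rule takes the 10 largest rises and the 10 largest falls among genes past the threshold whose BEZ235 values all lie on one side of the DMSO values; up to 3 members of each list with the largest change past the threshold; and 9 genes fixed in advance, of which 8 had a feature of their own. It leaves out uncharacterised, small RNA and pseudogene symbols and names 117 genes. Where 5 or fewer members of a list moved against the rest, some are named as well. Named too are TSC1 beside TSC2, further higher members of the FOXO list and dim members of the interferon list. These additions were chosen after their values were seen.

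The tests were tried on simulated arrays with the real feature means and 200 of 67528 features changed, drawn 10 times with different seeds. With variances drawn from the fitted prior, on average 75.2% of features changed by 0.5 (log2), 95.5% of those changed by 1 and 99.8% of those changed by 2 were called, and 4.65% of all calls were false, from 2.67% to 7.88% by draw. With each feature's moderated variance in place of the prior, the recovered share at 0.5 was 89.9%, and 7.35% of calls were false, from 4.52% to 12.3% by draw. With those variances and the trend and robust fit, 8.95% of calls were false, from 4.90% to 15.0% by draw. In both of these settings the false share over all draws exceeded the nominal 5%. The simulated features were drawn independently and 200 were changed, whereas 12028 were called in the data. These shares may therefore not carry over to the calls below. In 1 simulated set of 36 lists of 30 genes, the list shifted by 0.3 was called and 0 of the unshifted lists were. Genes in these lists were drawn independently, so the result does not show how the list test behaves when genes are correlated.

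Alternatives were centring each array on its median, quantile normalization of the deposited values, a filter at the median level of all features, eBayes with trend and robust estimation, array weights, the replicate number as a block, each array left out in turn, only features with 1 symbol, the mean of all features of a gene, limma's treat against a fold change of 1.2, the estimated correlation and fry. Cyclic loess normalization, features with distinct values only, and lists without shared members were added after the values had been seen. Where a call is counted over 17 alternatives, or a range over the alternatives is given, treat, the estimated correlation and fry are left out.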

Results

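TC71 is an established human Ewing sarcoma cell line, a tumour type driven by the EWSR1-FLI1 fusion. BEZ235 (dactolisib) inhibits the catalytic sites of PI3K and mTOR, the kinases that couple growth factor and nutrient signals to protein synthesis. Gene-level signal was measured on 6 arrays, 3 of cells given BEZ235 for 16 h and 3 of cells given DMSO, the solvent, to find the transcripts that differ under the inhibitor. Principal component 1 carried 71.3% of the variance and separated the treatments. Arrays correlated with r from 0.996 to 0.998 within a group and from 0.987 to 0.990 between groups, across features.

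After 16 h of BEZ235, 24 of 26 measured genes of amino acid synthesis and ATF4 signalling, all 35 of mitosis and 17 of 21 of the unfolded protein response fell past adjusted p under 0.05 in limma's test, and 19 of 30 ribosome biogenesis genes rose. ASNS, the asparagine synthetase, fell by 3.49 on the log2 scale (SE 0.062; 11.17 ± 0.08 under DMSO and 7.68 ± 0.08 under BEZ235, SD, n = 3 each). SLC7A11, the cystine importer, fell by 3.67 (SE 0.060) and CDK1, the kinase that drives entry into mitosis, fell by 2.41 (SE 0.070). UTP20, a component of the small-subunit processome, rose by 1.30 (SE 0.117) and HNRNPM, an RNA-binding splicing regulator, by 1.77 (SE 0.087). In the same arrays, 17 of 22 features placed on the mitochondrial chromosome by their identifiers fell and 0 rose, with a median log2 fold change of -0.32.

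Of 67528 features, 12028 (17.8%) passed adjusted p under 0.05 in limma's test, 6320 higher and 5708 lower under BEZ235. With each array centred on its median, the higher calls made up 39.8% of all calls, against 52.5% with the values as deposited, so the balance of rises and falls depends on the scaling. At least 2-fold changes were found for 300 features upward and 543 downward, and with only the features of 1 gene symbol tested for 97 upward and 347 downward. Counted over 22465 named genes, 3240 were higher and 3420 lower. In all 6660 of these genes the 3 BEZ235 values lay on one side of the 3 DMSO values. Passing this test with 3 arrays against 3 nearly forces such a separation, so it adds no support to the calls. Over all genes, the called ones included, it held for 47.7%, against 10% by chance in a 3 against 3 design.

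The largest fall among named genes was that of ESRP1, an epithelial splicing regulator, at -4.50 (SE 0.088, adjusted p = 4.17e-07), from 9.67 ± 0.03 to 5.17 ± 0.19 (SD, n = 3 each). The BEZ235 level lies below the median level of all features (5.67), so the size of that fall is uncertain. CHAC1, a glutathione-degrading enzyme induced in the integrated stress response, fell by 3.43 (SE 0.053). FAM72D (-3.49) and FAM72C (-3.17) fell too, but are near-identical paralogs whose probes cannot be relied on to tell them apart. SPX, which encodes the peptide spexin, fell by 3.23, and PBK, a mitotic kinase, by 2.73. TNFRSF9, a receptor of the TNF family, fell by 2.98 (SE 0.043), and CXCL11, an interferon-inducible chemokine, fell by 2.72 (SE 0.062), also to a level below that median (4.37 ± 0.11).

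The largest rise among named genes was that of the long noncoding RNA LINC01963, at 2.19 (SE 0.180, adjusted p = 0.000117), from 5.24 ± 0.27 to 7.43 ± 0.32 (SD, n = 3 each). Its DMSO level lies below the median level of all features (5.67), so the size of that rise is uncertain. XKR4 rose by 1.91, MARVELD1 by 1.87, and PIK3CG, the catalytic subunit gamma of PI3K, by 1.80 (SE 0.084), from a low level of 5.37 ± 0.05. HNRNPM rose 3.41-fold, from 8.86 ± 0.18 to 10.63 ± 0.04 (adjusted p = 1.06e-05). UTP14A, another processome component, rose by 1.68 (SE 0.074), and NCOA5, a nuclear receptor coactivator, by 1.68 (SE 0.137). TMT1B (1.67), OLFM3 (1.61) and the noncoding LINC00539 (1.60) completed the set of 10.

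**Figure D1:**
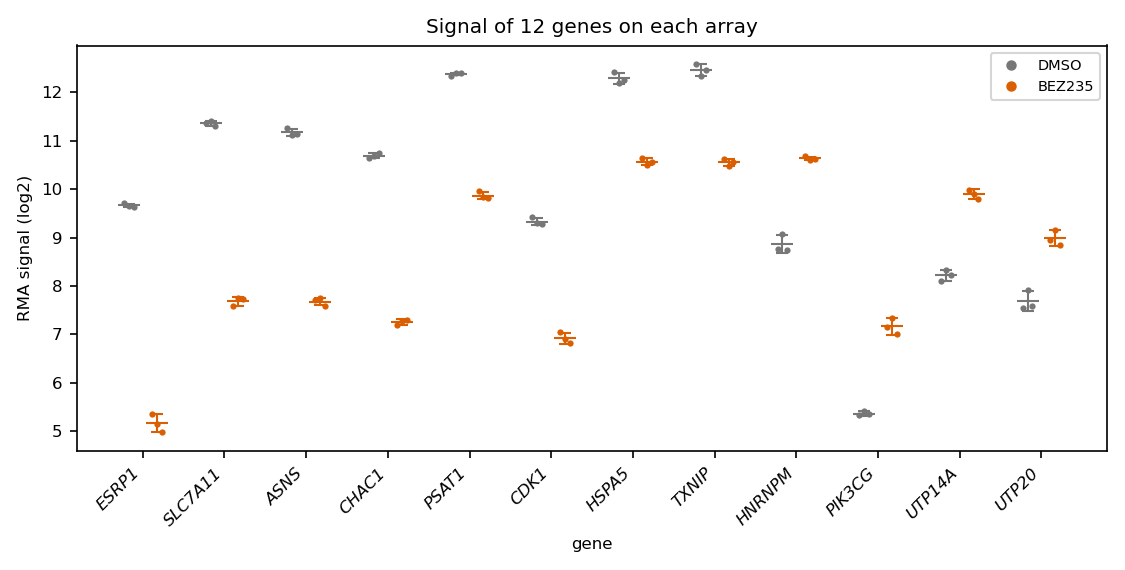
Signal of 12 genes on each of the 6 arrays (vertical axis, RMA signal on the log2 scale; horizontal axis, gene). Small points are single arrays, grey for DMSO and orange for BEZ235, bars are means and error bars the SD over 3 arrays; ESRP1 lies at 9.67 under DMSO and 5.17 under BEZ235, and HNRNPM at 8.86 and 10.63.

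Of 35 gene lists, 15 shifted lower and 2 higher by camera with the preset correlation; with a correlation estimated for each list, 0 passed in either direction. Camera compares a list with all other genes, and the estimated correlations were large for several lists on these 6 arrays. Both p-values are given below for the lists that passed, and the preset one alone for the others.

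Genes of amino acid synthesis and the targets of ATF4, the transcription factor of the integrated stress response, fell in 24 of 26 measured members, and in 25 when adjusted over the list alone (median -1.49, camera adjusted p = 2.74e-22, and adjusted p = 0.188 with an estimated correlation). PSAT1, an enzyme of serine synthesis, fell by 2.51 (SE 0.053). Amino acid transporters fell in 11 of 15 members, with 12 lower and 1 higher when adjusted over the list alone (median -0.75, adjusted p = 1.1e-08, and adjusted p = 0.21 with an estimated correlation). Besides SLC7A11, the cationic amino acid carrier SLC7A3 fell by 2.43 (SE 0.088) and SLC7A5, the large neutral amino acid carrier, by 1.44 (SE 0.057). Aminoacyl-tRNA synthetases, which charge tRNAs, fell in 9 of 15 members and rose in 2, HARS1 at 0.53 and RARS1 at 0.35. Adjusted over the list alone, 10 fell and 2 rose (median -0.34, adjusted p = 6.42e-05, and adjusted p = 0.482 with an estimated correlation). WARS1 fell by 1.59 (SE 0.049), AARS1 by 1.52 and YARS1 by 1.15.

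Genes of mitosis and G2/M fell in all 35 measured members, also when adjusted over the list alone (median -1.44, adjusted p = 8.25e-32, and adjusted p = 0.21 with an estimated correlation). Beside CDK1, NDC80, a kinetochore protein, fell by 2.20 (SE 0.090), and PRC1, which bundles spindle microtubules, fell by 1.82 (SE 0.088). Genes of DNA replication and G1/S fell in 28 of 41 members and rose in 1, PRIM1 (0.27). Adjusted over the list alone, 28 fell and 3 rose (median -0.52, adjusted p = 3.31e-14, and adjusted p = 0.438 with an estimated correlation). CLSPN (-1.67, SE 0.072), CDC6, which loads the replicative helicase (-1.41), and MCM10 (-1.39) fell most. Replication-dependent histones fell in 6 of 11 members, among them H1-2 (-0.73) and H4C3 (-0.69), while H2AC6 rose by 0.58. Adjusted over the list alone, 7 fell and 1 rose (median -0.28, adjusted p = 0.00458, and adjusted p = 0.513 with an estimated correlation). Histone genes resemble one another in sequence, so their signals can be shared.

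Genes of the unfolded protein response fell in 17 of 21 members, with 18 lower and 1 higher when adjusted over the list alone (median -0.54, adjusted p = 1.64e-11, and adjusted p = 0.287 with an estimated correlation). HSPA5, the main chaperone of the endoplasmic reticulum, fell by 1.72 (SE 0.068), HERPUD1 by 1.80 and HYOU1 by 1.71. The proteasome list fell in 20 of 32 members and rose in 4. Adjusted over the list alone, 23 fell and 6 rose (median -0.27, adjusted p = 1.82e-05, and adjusted p = 0.557 with an estimated correlation). NFE2L1, a transcription factor of proteasome genes, fell by 1.15 (SE 0.062), and the subunits PSMD14 by 0.79 and PSMB3 by 0.77. Targets of NRF2 and AhR fell in 10 of 17 members and in 11 when adjusted over the list alone (median -0.27, adjusted p = 4.65e-06, and adjusted p = 0.188 with an estimated correlation); GCLM, a subunit of the enzyme that starts glutathione synthesis, fell by 1.16 and the thioredoxin reductase TXNRD1 fell by 1.02. Targets of p53 fell in 13 of 20 members and rose in 1, TP53I3 (0.74). Adjusted over the list alone, 13 fell and 2 rose (median -0.43, adjusted p = 1.82e-05, and adjusted p = 0.188 with an estimated correlation). Among them GDF15, a stress-induced cytokine, had the largest fall at -2.36 (SE 0.073), with DDB2 at -1.41 and GADD45A at -1.29.

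Ribosome biogenesis genes rose in 19 of 30 members, with 0 lower. Adjusted over the list alone, 20 rose and 1 fell (median 0.31, adjusted p = 1.82e-05, and adjusted p = 0.513 with an estimated correlation). Beside UTP20, the rRNA processing factors RRP1B and RRP9 both rose by 0.81 (SE 0.049 and 0.075). Cytosolic ribosomal proteins rose in 14 of 46 members, with 0 lower and 18 higher when adjusted over the list alone (median 0.13, adjusted p = 0.000282, and adjusted p = 0.759 with an estimated correlation). RPS9 rose by 0.37 (SE 0.050), RPS14 by 0.32 and RPL10A by 0.32; these genes have many processed pseudogenes, so their signals are uncertain. The factors of translation initiation and elongation held 9 higher and 5 lower of 30 members (14 and 6 adjusted over the list alone) and the list did not pass (median 0.13, adjusted p = 0.279), though it did in 2 of 17 alternatives, quantile normalization (adjusted p = 0.0224) and cyclic loess normalization (adjusted p = 0.0298), over a range from 0.0224 to 0.478. EIF5 rose by 0.87 (SE 0.062) and EIF2S3 by 0.51, and EIF2B3 fell by 0.44.

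**Figure D2:**
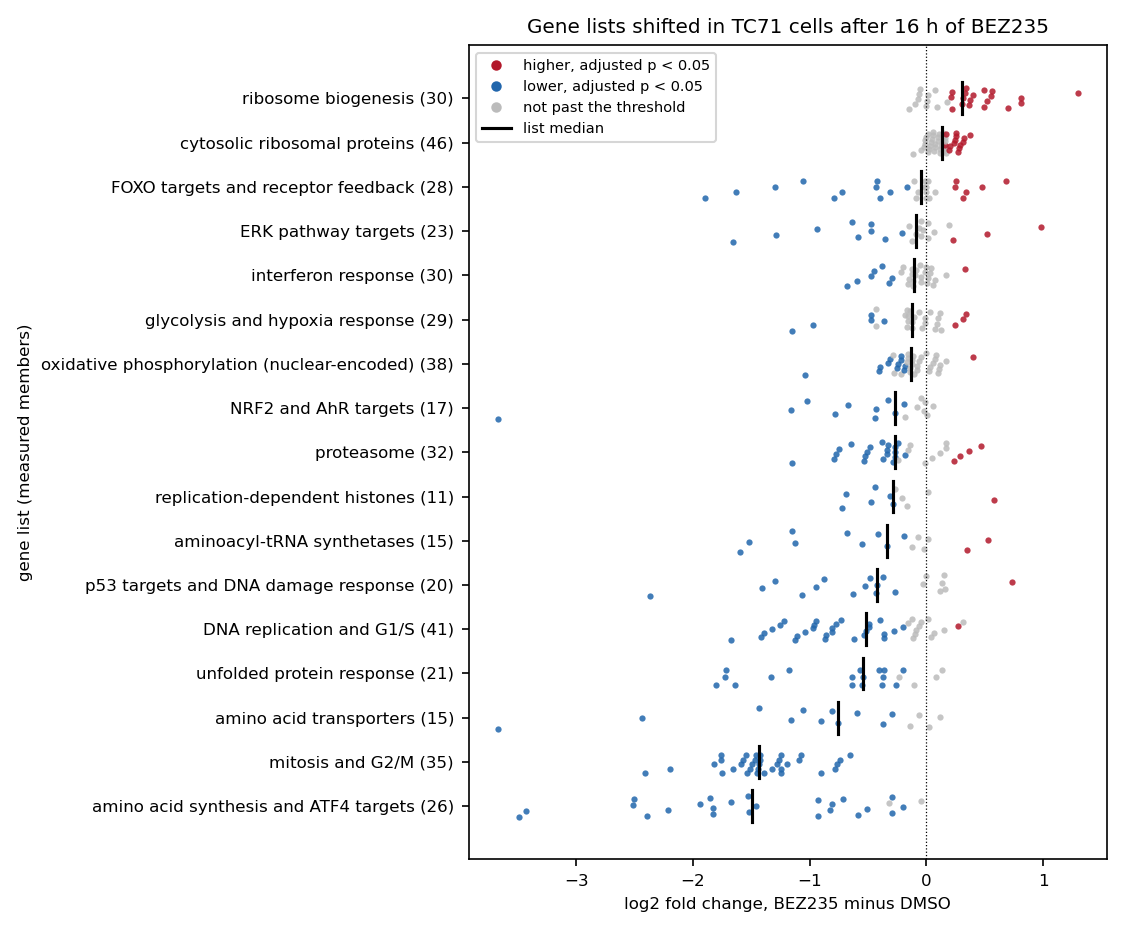
Log2 fold change, BEZ235 minus DMSO (horizontal axis), of each measured member of the 17 lists that passed by camera with the preset correlation (vertical axis, number of measured members in parentheses). Red and blue points are members higher and lower past the threshold, grey points are members that did not pass, and black bars are list medians, which run from -1.49 for amino acid synthesis and ATF4 targets to 0.31 for ribosome biogenesis.

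Of the components of the inhibited pathway, 6 were higher and 9 lower of 25 (6 and 11 adjusted over the list alone), and the list did not pass (median -0.10, adjusted p = 0.156). EIF4EBP1, the translation repressor that mTOR phosphorylates, fell by 0.78 (SE 0.061) and MTOR itself by 0.38 (SE 0.076), while TSC2, an upstream brake on mTOR, rose by 0.72 (SE 0.054), its partner TSC1 fell by 0.39 (SE 0.059) and PIK3R3, a regulatory subunit of PI3K, fell by 0.72 (SE 0.101). FOXO targets and receptor feedback genes held 6 higher and 11 lower of 28, also when adjusted over the list alone (median -0.05, adjusted p = 0.0209, and adjusted p = 0.513 with an estimated correlation). The insulin receptor INSR and its substrate IRS2 each rose by 0.25 (SE 0.046), ERBB3 fell by 0.17 (SE 0.043, adjusted p = 0.031), TXNIP, an inhibitor of glucose uptake, fell by 1.90 and SESN3, a sestrin, by 1.63. The FOXO call by camera was lost in 5 of 17 alternatives. Among these were the tests without DMSO replicate 1 (adjusted p = 0.052), with quantile normalization (adjusted p = 0.0718) and with the median-level filter (adjusted p = 0.0529). Another was the test without members shared with another list, such as GADD45A and SESN1. Over the alternatives the adjusted p ran from 0.0118 to 0.123 and the median from -0.10 to -0.02. The call for INSR was lost with each array centred on its median (adjusted p = 0.0564, range 0.00136 to 0.0564), and that for ERBB3 without any 1 of the 6 arrays (adjusted p from 0.0566 to 0.102) and with the replicate block (adjusted p = 0.0664; range 0.00632 to 0.102 over the alternatives). Autophagy and lysosome genes held 9 higher and 16 lower of 35 (10 and 16 adjusted over the list alone, median -0.09, adjusted p = 0.0601). WIPI1, which acts in autophagosome formation, fell by 1.48 (SE 0.142), the lysosomal galactosidase GLA by 1.00 and GABARAPL1 by 0.83. The autophagy list passed in 3 of 17 alternatives, without DMSO replicate 3 (adjusted p = 0.03), without BEZ235 replicate 1 (adjusted p = 0.0251) and with the replicate block (adjusted p = 0.0431), over a range from 0.0251 to 0.245.

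Lipid genes did not pass as lists. Cholesterol synthesis and uptake held 6 higher and 4 lower of 20 (8 and 4 adjusted over the list alone, median 0.17, adjusted p = 0.279), with TM7SF2 (1.25) and CYP51A1 (0.96), both enzymes of sterol synthesis, higher and STARD4 (-0.63) lower. Fatty acid synthesis held 2 higher, FASN (0.41) among them, and 2 lower, ME1 (-1.14) and SREBF1 (-0.27), of 14 (3 and 5 adjusted over the list alone, adjusted p = 0.662). Nucleotide synthesis held 7 higher and 9 lower of 23 (8 and 10 adjusted over the list alone, median -0.08, adjusted p = 0.358); ADSL, a purine synthesis enzyme, rose by 1.22 and TYMS, the thymidylate synthase, fell by 0.60. Glycolysis and hypoxia genes held 3 higher and 5 lower of 29 (3 and 9 adjusted over the list alone, median -0.12, adjusted p = 0.0372, and adjusted p = 0.817 with an estimated correlation), with VEGFA at -1.15 and the glucose transporter SLC2A3 at -0.97. That call was lost in 8 of 17 alternatives, among them without DMSO replicate 1 (adjusted p = 0.0547) and without BEZ235 replicate 3 (adjusted p = 0.201), over a range from 0.00595 to 0.201 and with medians from -0.17 to -0.05. Nuclear-encoded genes of oxidative phosphorylation held 1 higher, NDUFB10 (0.40), and 11 lower of 38 (1 and 14 adjusted over the list alone, median -0.13, adjusted p = 0.00123, and adjusted p = 0.648 with an estimated correlation), led by CYCS, cytochrome c, at -1.04.

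Splicing factors moved in both directions at the level of whole genes. The hnRNPs and splicing regulators held 8 higher and 11 lower of 37 (9 and 13 adjusted over the list alone, median -0.07, adjusted p = 0.139); HNRNPM and ESRP1 had the largest changes, and MBNL2 fell by 0.66 (SE 0.057). SR proteins and their kinases held 6 higher and 3 lower of 23 (9 and 5 adjusted over the list alone, median 0.07, adjusted p = 0.329). SRSF3 rose by 1.10 (SE 0.065) and SRSF6 by 0.69, and CLK1, a kinase of SR proteins, fell by 0.71. The core spliceosome held 13 higher and 7 lower of 35 (13 and 8 adjusted over the list alone, adjusted p = 0.489), with DDX23 at 0.64 and SNRPG at -0.83; its median of 0.03 turned negative with each array centred on its median. Exon usage was not tested, because the features tested are whole transcript clusters.

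Genes that EWSR1-FLI1 activates held 5 higher and 8 lower of 28 (6 and 8 adjusted over the list alone, adjusted p = 0.55), among them PAPPA (0.91) and DKK2 (0.87) higher and IL1RAP (-0.68) lower. Genes it represses held 4 higher and 6 lower of 24 (5 and 7 adjusted over the list alone, adjusted p = 0.55), with ANXA1 at -0.93. MYC was higher by 0.23 (SE 0.047, adjusted p = 0.0109), a call lost with each array centred on its median (adjusted p = 0.0732, range 0.00231 to 0.0732), and CCND1, cyclin D1, did not pass (-0.12, SE 0.050, adjusted p = 0.163). Targets of the ERK pathway held 3 higher and 9 lower of 23 (4 and 9 adjusted over the list alone, median -0.09, adjusted p = 0.0102, and adjusted p = 0.648 with an estimated correlation); JUN fell by 1.65 (SE 0.057), while DUSP6, an ERK phosphatase, rose by 0.98 (SE 0.073). Genes of the BCL2 family and its effectors held 1 higher, BOK (1.15), and 6 lower of 21 (2 and 7 adjusted over the list alone, median -0.04, adjusted p = 0.0814), with PMAIP1, which encodes NOXA, at -2.56 (SE 0.092). That list passed without BEZ235 replicate 1 (adjusted p = 0.0425), over a range from 0.0425 to 0.204. Heat shock proteins held 6 higher and 4 lower of 20 (8 and 5 adjusted over the list alone, adjusted p = 0.719), among them HSPH1 (0.49) and HSPA9 (-0.55).

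Interferon response genes held 1 higher, RSAD2 (0.34), and 7 lower of 30, also when adjusted over the list alone (median -0.10, adjusted p = 0.00707, and adjusted p = 0.462 with an estimated correlation). HLA-B (-0.68) and HLA-C (-0.60), which present peptides to T cells, and IFI44 (-0.48) led it. The HLA genes are each represented by several features on alternate haplotypes, so their signals are uncertain. RSAD2 (4.65 under DMSO and 4.98 under BEZ235), IFIT1 (4.60 and 4.31) and IFIH1 (5.65 and 5.33) passed at levels below the median of all features (5.67). The sizes of their changes are uncertain. Neural genes held 7 higher and 6 lower of 24 (8 and 7 adjusted over the list alone, adjusted p = 0.615), with the adhesion molecule NCAM1 at -1.13 and the neurofilament NEFM at -0.80. Markers of other cell types were measured beside these groups. Blood cell markers (14 measured, median 0.04, negative with each array centred on its median, adjusted p = 0.425) and endothelial markers (12 measured, median 0.05, adjusted p = 0.55) had 0 members past the threshold. Fibroblast markers held 3 higher and 4 lower of 16 (adjusted p = 0.55; the same numbers adjusted over the list alone), with MMP2 at 0.95 and ACTA2 at -1.11, and epithelial markers 1 higher, MUC1 (0.32), and 2 lower, ESRP1 and OCLN (-0.36), of 16 (2 and 3 adjusted over the list alone, adjusted p = 0.815). For fatty acid synthesis, the genes repressed by EWSR1-FLI1, the neural list and the epithelial markers the median was slightly positive while the mean and the test were negative, and for each of these 4 the median changed sign under at least 1 scaling of the arrays.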

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

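The comparisons with cyclic loess normalization and with distinct values were added after the values had been seen; what each test below would show was written after the patterns had been seen and before the result of that test was known.

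Entries of the table outside the transcript clusters also differed between the treatments. Among 1465 single probe selection regions and junctions, 412 passed adjusted p under 0.05 in limma's test, 312 higher and 100 lower under BEZ235, with a median log2 fold change of 0.09. Among 1343 numbered control entries, 214 passed, 136 higher and 78 lower, with a median of 0.04. In contrast, 0 of 23 antigenomic background entries (median -0.01), 2 of 155 spike-in entries of the ERCC type and 0 of 4 poly-A controls (median -0.22) passed, nor did any of 4 hybridisation controls (median -0.25). The numbers of poly-A and hybridisation controls are small, and their medians are below 0.

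The first pattern is the size of the response, 12028 features. Of the 10 splits of the 6 arrays into 3 and 3, the real split gave 12028 features and the highest of the others 0. Each other split mixed DMSO and BEZ235 arrays within its groups, so the difference between treatments enlarged the spread there. A low count was therefore bound to follow, whatever the cause of that difference. In addition, 10 splits are too few for a share under 0.05. After cyclic loess normalization, which removes shifts that depend on intensity, 11644 features passed, so such a shift is not the whole cause. With features of identical values counted once, 11913 passed. Of the 12028 calls, 11738 were on those features, so leaving out exact copies could not have lowered the count much. Near copies with slightly different values stayed in and were not tested. The labels name no batch, so none was tested.

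The second pattern is the rise of ribosome biogenesis genes, a group that growth signalling through mTOR is generally held to promote. An intensity-dependent shift would leave the list within the range of other genes of the same level, but its median of 0.31 lay at percentile 100 of 10000 matched lists, whose central 95% ran from -0.16 to 0.11. No single array decides it: with each array left out in turn, the lowest median was 0.277. A candidate explanation that remains open is a change relative to a falling total of RNA, which equalised arrays cannot show, beside an effect of BEZ235 on these genes; the list does not pass with an estimated correlation (adjusted p = 0.513).

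The third pattern is the lower signal of the mitochondrial chromosome features, with 17 of 22 lower and group means of 12.03 ± 0.10 under DMSO and 11.53 ± 0.06 under BEZ235 (SD, n = 3 each). Their median of -0.32 lay at percentile 0.01 of 10000 sets matched on level, against a central 95% from -0.15 to 0.12. A shift shared by all features of the same bins of level does not account for it. The bins hold equal numbers of features and span wide ranges at the top. A shift of only the brightest features is therefore not excluded. The random sets also take no account of correlation among the 22 features. With each array left out in turn, the highest median was -0.277, so no single array decides it. The poly-A and hybridisation controls had medians of -0.22 and -0.25, the same direction as these features, with 0 of 4 past the threshold in each. An effect of BEZ235 on mitochondrial transcripts remains a hypothesis, and a difference in RNA handling between the treatments remains open.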

How the results depend on the processing

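None of the 12028 calls changed sign in any alternative that was run on features. The number of features past the threshold stayed within 1.5 times, from 8471 to 12844, except against a fold change of 1.2. There treat called 3439 (1474 higher, 1965 lower), a stricter question by construction. The 8471 were found among the 23781 features with 1 symbol, and the median-level filter also tested fewer features, so those counts are not like for like with 12028 of 67528. Features with 1 symbol only gave 444 at least 2-fold changes (97 higher, 347 lower), with fewer features tested. Lists called with an estimated correlation were 0 higher and 0 lower, since that correlation widens the test. By contrast, fry, which does not compare a list with other genes, called 4 higher and 22 lower. It called 10 lists that had not passed in the main setting and lost 1 that had. The calls kept were 9999 with each array centred on its median and 10822 with cyclic loess, where 39.8% and 45.2% of calls were higher. Of the named genes, MYC and INSR lost their call with centring. Centring lowered every log2 fold change by the same amount, that of MYC from 0.23 to 0.18 and that of INSR from 0.25 to 0.20. Leaving out 1 array gave 9229 to 11171 features, 799 to 921 at least 2-fold, and 13 to 17 lists lower with 2 higher in each case. The labels do not say whether arrays with the same replicate number form pairs. The correlations of same-numbered deviations were -0.23, -0.09 and 0.14, and 1 array correlated best with its own number. With so few arrays these values cannot show whether pairs exist. With the replicate block, 10237 features passed (9866 of the 12028 calls), ERBB3 no longer passed (adjusted p = 0.0664) and the autophagy list did (0.0431). No detection call limits dim features; at or above the median level, 11538 passed.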

Other observations

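The tests in this part were chosen after the largest changes had been seen, and the members of each list were written down before the values of that list were looked at; all 3 lists tested are reported. They were tested with limma's camera and the correlation preset at 0.01, and p-values are given without adjustment unless stated.

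Several genes of the primary cilium, a sensory projection found mostly on non-dividing cells, stood among the largest rises outside the named set: DYNC2H1 (1.49, SE 0.111), CC2D2A (1.48, SE 0.062) and TCTN2 (1.27, SE 0.084), with the axonemal dynein chain gene DNAI3 (1.41, SE 0.074) beside them. Of 47 measured genes of a wider list that leaves those 4 genes out, 24 were higher and 4 lower, with a median of 0.22. RPGRIP1L rose by 1.11 (SE 0.090), BBS1 by 0.84 and DYNC2I1 by 0.84, the last a subunit of the dynein that moves cargo within cilia. BBS7 fell by 0.31. The hypothesis that cilium genes as a group may rise with BEZ235 was met with the preset correlation (p = 8.88e-06, adjusted over the 3 lists 1.87e-05) and not with an estimated one (p = 0.2). Its median lay at percentile 100 of 10000 lists matched on level. Whether the cells formed cilia was not measured.

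Falls of TNFRSF9, CXCL11 and CXCL10 (-2.19, SE 0.076) led to the hypothesis that targets of NF-kappaB might fall together. Among 23 measured targets without those genes, 12 were lower and 2 higher, with a median of -0.29 and p = 1.25e-05 (adjusted over the 3 lists 1.87e-05), and p = 0.0832 with an estimated correlation. CXCL8, which encodes interleukin 8, fell by 1.51 (SE 0.158), IL32 fell by 1.47 (SE 0.075) and VCAM1 fell by 0.71, while CCL2 rose by 0.40 and TNFAIP2 by 0.15. NFKBIA, the inhibitor that NF-kappaB induces, fell by 0.52.

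Noncoding host genes of small nucleolar RNAs are in many cases degraded by a pathway that needs translation, so lower translation could raise them. In limma's camera test the p was 0.318 both before and after adjustment over the 3 lists (adjusted p = 0.318). DANCR (0.31) and EPB41L4A-AS1 (0.47) were higher, 2 of 5 measured genes, and 0 were lower. A p of 0.05 or more had been set beforehand to count against the hypothesis; it is not read so here, because only 5 of 22 listed genes had a feature with 1 symbol, too few to decide. That reading was chosen after the result was seen.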
